A study of Homo sapiens with 18 samples.

How the data were processed

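RNA was sequenced from 2 human colorectal cancer cell lines, LoVo and DLD-1. Each line was given an empty vector (EV) or was made to overexpress LIN28B, and a further set of LIN28B cells received alpelisib, an inhibitor of the alpha isoform of phosphatidylinositol 3-kinase (PI3K), at 5 µM. The 6 groups held 3 libraries each, 18 in all, and each library was assigned to its group and replicate number from its label. Per the labels' protocols, cells grew in DMEM with serum, total RNA was purified on RNeasy columns, and poly(A) RNA was enriched with oligo(dT) beads before NEBNext Ultra II library preparation. The length of the alpelisib treatment and the vehicle given to untreated cells were not given in the sources used here. Nothing in the labels states that the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

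The deposited values were TPM, which are length-scaled shares of each library, 1 value per gene and library, per the file headers. The submitters' processing notes name the genome build hg38 and the tools STAR 2.7.10, Picard, HTSeq and DESeq2, without their role or order. The annotation release, the use of strand in counting and the gene lengths behind the TPM were not given in the sources used here. TPM fixes the total of each library, so a large change in a few abundant transcripts shifts all other values the opposite way, and an error in a gene's length changes its level in all libraries alike. TPM keeps no record of sequencing depth, so the depth of each library is unknown, no counting interval can be given, and no count model was used. The table listed 61806 Ensembl gene identifiers, of which 61757 were matched to a symbol in the reference gene name table, and all columns were used. Symbols are used as names throughout. No 2 libraries held identical values, and Pearson's r of log2(TPM + 1) between replicates of a group lay between 0.9673 and 0.9831 across genes, which are not independent replicates.

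Genes with a TPM of 1 or more in at least 3 of the 18 libraries were kept, which left 18537. Of these, 2764 were listed at 0 in at least 1 library. The values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend), in 1 linear model of 6 groups with 12 residual degrees of freedom and 3.98 prior degrees of freedom. All groups shared the estimate of spread. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested within a comparison, and a gene was called at an adjusted p under 0.05. A fold change is on the log2(TPM + 1) scale and so understates the change of low genes. Ratios of mean TPM are given as folds where stated. The comparisons were LIN28B versus EV, alpelisib versus untreated LIN28B cells, and LIN28B with alpelisib versus EV, each within a line, and the differences of the first and of the second effect between the lines.

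Before the data were examined, 42 gene lists, the tests of the comparisons and lists, most alternatives and a rule for the genes named were fixed. The rule took, for LIN28B versus EV and for alpelisib in each line, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap, whose mean reached 2 TPM in 1 of the groups and whose symbol was not a clone name, and the 5 largest in each direction for the differences between lines. It added genes fixed in advance in each comparison, among them LIN28B, LIN28A, HMGA2, IGF2BP1, IGF2BP2, IGF2BP3, PIK3CA, PIK3CB, PIK3R1, AKT1, AKT2, CLDN1, NOTCH3, IRS2, INSR and ERBB3, and up to 4 members with the smallest p of a list described. Some genes that met the rule are not reported here. Without overlap between groups, chance alone gives 10% of genes for 3 libraries against 3. A list was tested with camera at a preset correlation of 0.01 between its genes, again with an estimated correlation, and with fry, and 40 lists with at least 5 genes tested entered. Camera p-values were adjusted over the lists within a comparison. With an estimated correlation, no list was called in LIN28B versus EV or alpelisib versus untreated in either line, so that the camera calls rest on the preset value. Under median-of-ratios scaling and an estimated correlation, camera did call lists. These were enterocyte markers (adjusted p = 0.0265) and MHC class I presentation (0.0156) for LIN28B versus EV in LoVo, and mitosis, MHC class I presentation and TGF-beta target genes (0.0124 each), DNA replication and G1/S (0.0252) and the ATF4 and amino acid response (0.0354) for the same in DLD-1. The MHC class I presentation list, as fixed, also held the MHC class II genes CIITA, HLA-DRA, HLA-DMA and CD74. For alpelisib the lists called were mitosis and fatty acid synthesis under the LoVo label (0.0259 each by camera) and 0 lists in DLD-1. Members of a list were also adjusted over the list alone.

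Scaling by the median of ratios to the geometric mean was an alternative to TPM as deposited, and its shift of the median of all genes is given where it exceeded 0.1 log2. The other alternatives were a pseudocount of 0.1, no filter, a filter at a TPM of 5, quantile normalization, a replicate block, array quality weights, a fit of only the groups compared, a fold minimum of 1.5, and leaving out each library in turn. Added after seeing the data were a correction for GC content and transcript length fitted per library, a fit without mitochondrially encoded genes, and one without LoVo EV replicates 1 and 2 together. GC content and length were taken from GENCODE 29 for 17999 of the genes tested (97.1%). For positions along the genome, median differences were taken over 131 bins of 25 Mb with at least 20 genes, and their SD was set beside 1000 shuffles of the genes between bins, both chosen after seeing the data. Overlaps of called genes were tested with Fisher's exact test beside the overlap of independent lists, and correlations of effects that share libraries were set beside a simulation of unchanged groups in 50 draws. Fisher's exact test treats genes as independent, which they are not, so its p-values do not measure the spread between samples. The simulation drew each gene independently. The fit was tested on simulated data for each comparison. It recovered 10.4% (alpelisib difference) to 47.8% (LIN28B versus EV in DLD-1) of 1.5-fold changes, 43.3 to 74.6% of 2-fold and 77.3 to 98.5% of 4-fold changes, with 3 to 13 calls among 18337 unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Antisense genes, genes inside other genes, paralogs and pseudogenes may share reads with their partners under the unstated counting and are reported as uncertain or left out.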

Results

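The data were poly(A)-enriched RNA-seq profiles of LoVo and DLD-1 cells, both derived from human colorectal adenocarcinomas. LIN28B is an RNA-binding protein that blocks the maturation of let-7 microRNAs, and PI3K passes growth factor signals to the kinase AKT. Each line was profiled as EV, as LIN28B, and as LIN28B with 5 µM alpelisib, with 3 libraries each. The libraries held 23010 to 25501 genes above 0 TPM, and their sequencing depth is unknown.

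LIN28B (ENSG00000187772; GRCh38 chromosome 6, 104936616 to 105083332, plus strand) was read first, as a check of the labels. In LoVo EV it measured 4.91, 3.66 and 3.87 TPM, and in the libraries labelled LoVo LIN28B 706, 682 and 674 TPM. With alpelisib it measured 146, 160 and 155 TPM. DLD-1 EV had 2.74, 1.17 and 1.38 TPM, DLD-1 LIN28B 493, 483 and 408 TPM, and DLD-1 LIN28B with alpelisib 150, 139 and 141 TPM. The group means were thus 4.15 ± 0.668, 687 ± 16.6 and 154 ± 7.14 TPM in LoVo and 1.76 ± 0.853, 462 ± 46.3 and 143 ± 5.68 TPM in DLD-1 (SD, n = 3). Each LIN28B library lay above each EV library of its line, and each untreated LIN28B library above each alpelisib library. The fold of LIN28B over EV was 166 in LoVo and 262 in DLD-1, and the log2 change was 7.07 in LoVo (limma, adjusted p = 1.46e-14).

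**Figure D1:**
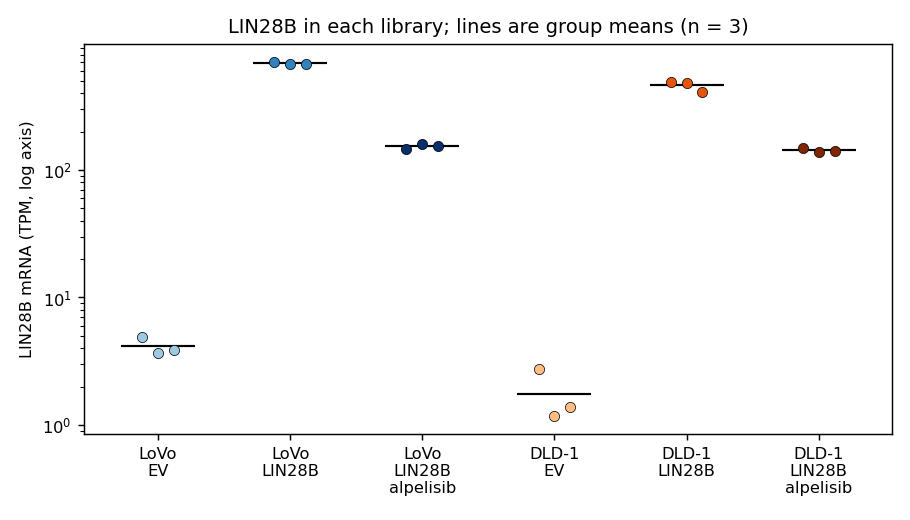
LIN28B level in each library, in TPM on a log axis, by line and group; points are libraries and lines are group means (n = 3). The EV libraries sit between 1.17 and 4.91 TPM, the untreated LIN28B libraries between 408 and 706 TPM and the alpelisib libraries between 139 and 160 TPM.

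The relations between groups were then compared, because the libraries labelled LoVo LIN28B resembled DLD-1 more than LoVo EV. They were not identical to DLD-1 either. KRT20, an intestinal keratin chosen after its values were seen, separated LoVo-labelled LIN28B from DLD-1 LIN28B, at 4.72 ± 0.347 against 114 ± 3.46 TPM (SD, n = 3; log2 difference -4.33, limma, adjusted p = 1.8e-12), as did CDX2, an intestinal transcription factor chosen in the same way, at 402 ± 53.8 against 227 ± 27.5 TPM (0.82, limma, adjusted p = 0.000494).

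Across all genes, limma called 10530 of 18537 genes (56.8%) between LoVo-labelled LIN28B and LoVo EV, 10294 (55.5%) between LoVo EV and DLD-1 EV, and 2592 (14%) between LoVo-labelled LIN28B and DLD-1 LIN28B. Pearson's r across genes, which are not independent replicates, ranged from 0.8904 to 0.9176 between LoVo EV and LoVo-labelled LIN28B libraries and from 0.9636 to 0.968 between LoVo-labelled LIN28B and DLD-1 LIN28B libraries. The SD over 131 bins of the genome of the median difference, after correction for GC content and length, was 0.146 log2 between LoVo-labelled LIN28B and LoVo EV and 0.148 between DLD-1 EV and LoVo EV. It was 0.0332 between DLD-1 LIN28B and DLD-1 EV and 0.0552 between LoVo-labelled LIN28B and DLD-1 LIN28B. With genes shuffled between bins the mean SD was 0.0812, 0.0817, 0.0279 and 0.0377 in the same order, and 0, 0, 8 and 0 of 1000 shuffles were as large. The labels were kept as given, and each direction below between LoVo EV and the other LoVo-labelled libraries rests on labels whose line could not be checked. So does each overlap below between the lines, which may not be one between separate lines.

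**Figure D2:**
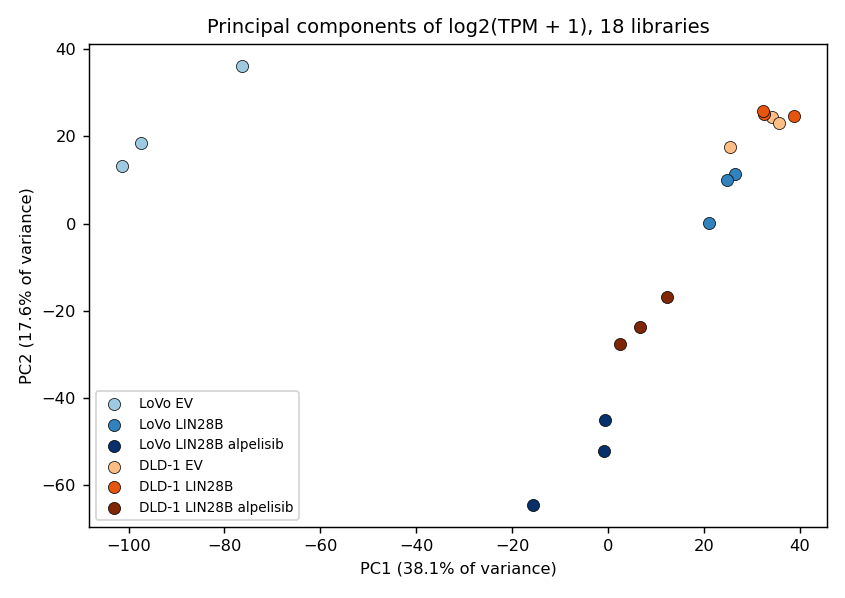
Principal components 1 (38.1% of variance) and 2 (17.6%) of log2(TPM + 1) for the 18 libraries, coloured by group. On component 1 the LoVo EV libraries sit between -101.3 and -76.44 and the libraries labelled LoVo LIN28B between 20.99 and 26.44, near DLD-1 EV at 25.49 to 35.56.

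**Figure D3:**
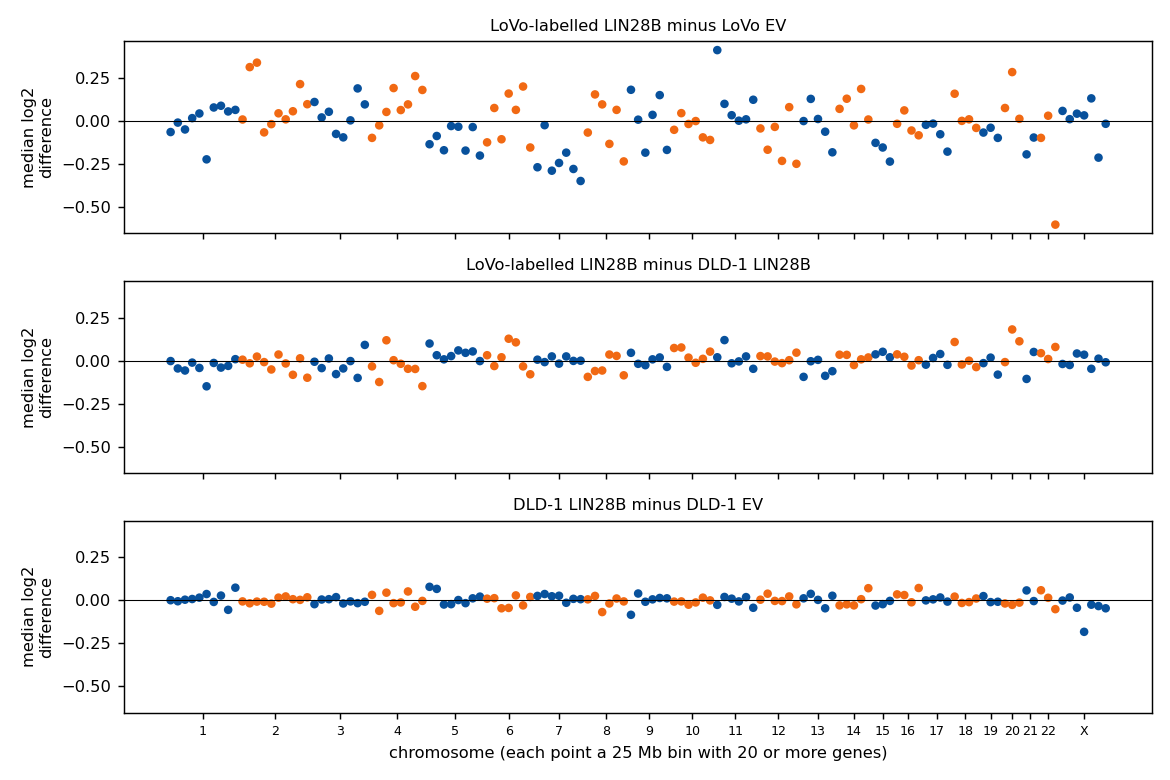
Median log2 difference of genes in 131 bins of 25 Mb in genome order, corrected for GC content and length, in 3 panels; points are bins. The SD over bins is 0.146 for LoVo-labelled LIN28B minus LoVo EV, 0.0552 for LoVo-labelled LIN28B minus DLD-1 LIN28B and 0.0332 for DLD-1 LIN28B minus EV.

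LIN28B versus EV in DLD-1 asked what LIN28B overexpression changed in that line. PSCA, a surface glycoprotein, fell from 14.6 ± 2.12 to 2.85 ± 0.93 TPM, TMPRSS4, a membrane serine protease, from 25.6 ± 1.03 to 8.95 ± 0.749 TPM, and TGFB2, a ligand of the TGF-beta family, from 35.0 ± 0.488 to 14.2 ± 0.537 TPM (SD, n = 3). ASNS, the asparagine synthetase, rose from 28.8 ± 6.68 to 81.1 ± 24.9 TPM and CHAC1, which degrades glutathione, from 7.36 ± 1.93 to 30.8 ± 14.8 TPM. HMGA2, a chromatin protein whose mRNA is a known let-7 target, rose 1.85-fold, from 18.4 ± 0.977 to 34.0 ± 3.58 TPM.

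By limma, adjusted p was 6.91e-05 for PSCA (log2 -2.04), 3.44e-05 for TMPRSS4 (-1.42), 0.000213 for TGFB2 (-1.25), 0.00835 for CHAC1 (1.81), 0.000862 for ASNS (1.44) and 0.00089 for HMGA2 (0.85). PCP4, a calmodulin-binding peptide, fell by 1.24 log2 (130 ± 11.6 to 54.4 ± 3.32 TPM, limma, adjusted p = 3.99e-07), ALDH1L1, a folate enzyme, by 1.25 (limma, adjusted p = 0.000862) and SEMA5A, a semaphorin, by 1.21 (limma, adjusted p = 0.00394). DPEP1, a membrane dipeptidase, rose from 3.30 ± 0.808 to 10.6 ± 0.322 TPM (1.45, limma, adjusted p = 9.85e-05), LCN15, a lipocalin, from 12.2 ± 3.6 to 36.0 ± 3.87 TPM (limma, adjusted p = 9.81e-05) and KRT34, a keratin, from 0.0224 ± 0.0388 to 2.10 ± 0.593 TPM (limma, adjusted p = 0.000213). IGF2BP2, an mRNA-binding protein, rose from 60.9 ± 1.95 to 82.6 ± 3.72 TPM (limma, adjusted p = 0.00531). S100A9, a calcium-binding protein, fell by 1.63 log2 (limma, adjusted p = 0.01), a call that ended without DLD-1 EV replicate 2 (adjusted p = 0.0575). In a fit of only the groups compared, CHAC1 (adjusted p = 0.118), ASNS (0.0802) and LCN15 (0.0517) were no longer called.

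**Figure D4:**
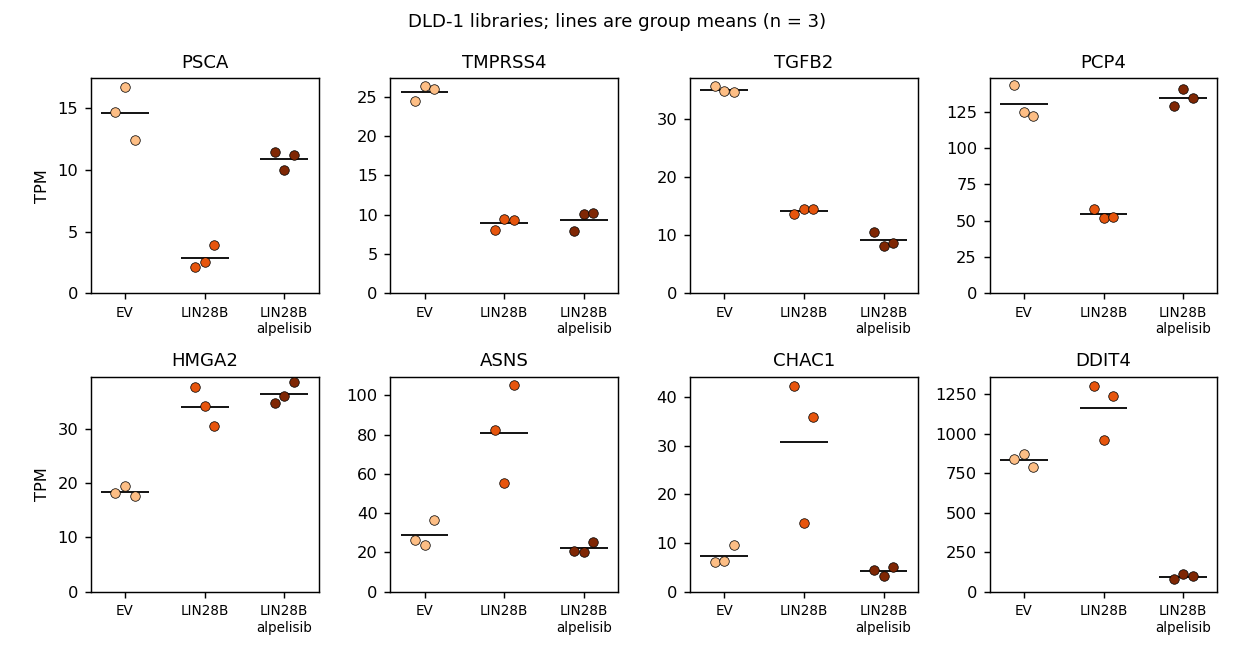
Levels of 8 genes in TPM in the DLD-1 EV, LIN28B and LIN28B alpelisib libraries; points are libraries and lines are group means (n = 3). PSCA, TMPRSS4, TGFB2 and PCP4 are lower in LIN28B than in EV, for TGFB2 at 14.2 against 35.0 TPM, while DDIT4 is at 1164 TPM in LIN28B and 96.2 TPM with alpelisib.

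Genes of the ATF4 and amino acid response, which cells induce when amino acids run short, rose in DLD-1 LIN28B: 19 of 36 were called higher and 0 lower (26 higher and 0 lower adjusted over the list alone), with a median log2 change of 0.60. Camera gave adjusted p = 3.25e-24 for this list and adjusted p = 0.139 with an estimated correlation. SLC7A5, an amino acid transporter, rose by 0.88 log2 (limma, adjusted p = 0.0013). Mitosis genes rose in 7 of 34 (28 of 34 adjusted over the list alone, median 0.43, camera adjusted p = 2.61e-23), among them TTK by 0.82 and AURKB by 0.62, both mitotic kinases, and DNA replication and G1/S genes in 10 of 42 (25 of 42 adjusted over the list alone, median 0.42, camera adjusted p = 8.26e-19). With an estimated correlation the 2 lists had adjusted p = 0.139 and adjusted p = 0.204. Of the let-7 target mRNAs, 6 of 37 rose and 0 fell (8 and 1 adjusted over the list alone), HMGA2 and IGF2BP2 among them (camera, adjusted p = 6.07e-07, and adjusted p = 0.285 with an estimated correlation).

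Other groups fell in DLD-1 LIN28B. Of the TGF-beta target genes 6 of 22 fell and 0 rose (6 and 1 adjusted over the list alone), TGFB2 and JUNB, a transcription factor, among them (camera, adjusted p = 0.000144, and adjusted p = 0.139 with an estimated correlation). Genes of the MHC class I presentation list, which also held class II genes, fell in 5 of 19 (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.32e-06) and interferon response genes in 3 of 34 (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000144), with UBE2L6, a conjugating enzyme of ISG15, at -0.81 log2 (limma, adjusted p = 0.00345). With an estimated correlation these lists had adjusted p = 0.139 and adjusted p = 0.219. Of the PI3K/AKT/mTOR components 1 of 39 was called (1 adjusted over the list alone, camera adjusted p = 0.856): PIK3CA measured 11.8 ± 1.28 and 11.7 ± 1.1 TPM, PIK3R1 19.6 ± 1.19 and 20.2 ± 0.804 TPM, and AKT1 97.5 ± 6.88 and 99.9 ± 1.7 TPM in EV and LIN28B (limma, adjusted p = 1, 0.97 and 0.932). CLDN1, a tight junction protein, had a log2 change of 0.14 and NOTCH3 one of -0.47 (limma, adjusted p = 0.851 and 0.24).

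In all, limma called 469 genes in DLD-1, 225 higher and 244 lower, of which 24 and 25 changed 2-fold or more. The count was 208, 185 and 207 without DLD-1 EV replicates 1, 2 and 3 and 187, 229 and 189 without DLD-1 LIN28B replicates 1, 2 and 3, each with fewer samples. Under median-of-ratios scaling 260 genes were called higher and 383 lower.

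LIN28B versus EV under the LoVo label compared the libraries labelled LoVo LIN28B with LoVo EV. SUGCT, a mitochondrial CoA transferase, fell from 320 ± 21.5 to 1.84 ± 0.374 TPM, CD74, the MHC class II invariant chain, from 274 ± 14.4 to 2.50 ± 0.798 TPM, and CA9, a hypoxia-induced carbonic anhydrase, from 155 ± 11.8 to 3.19 ± 2.06 TPM (SD, n = 3), against the direction of most other hypoxia response genes. TFF3, a goblet cell peptide, rose from 0.702 ± 0.681 to 63.0 ± 1.79 TPM, the receptor kinase KIT from 0.540 ± 0.186 to 41.2 ± 3.08 TPM and the chloride channel CFTR from 2.99 ± 1.15 to 98.2 ± 3.77 TPM. HMGA2 went the other way from DLD-1, from 65.0 ± 9.04 to 25.3 ± 2.41 TPM, beside 18.4 ± 0.977 TPM in DLD-1 EV.

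By limma, adjusted p was 4.92e-10 for SUGCT (log2 -6.82), 5.56e-11 for CD74 (-6.32), 1.57e-10 for CA9 (-5.33), 1.06e-11 for TFF3 (5.32), 3.31e-14 for KIT (4.78), 1.04e-12 for CFTR (4.67) and 5.57e-08 for HMGA2. The cytokine genes CCL2 and LTB fell by 5.47 and 5.15 log2. SLC39A2, a zinc transporter, rose by 4.98 log2, NUPR1, a stress-induced regulator, by 4.75, TDO2, a tryptophan dioxygenase, by 4.38, and the chemokine CXCL5 by 4.12. PIK3CA measured 6.64 ± 1.8 TPM in LoVo EV and 15.0 ± 0.623 TPM in LoVo-labelled LIN28B (limma, adjusted p = 8.6e-06), PIK3R1 10.0 ± 2.54 and 23.2 ± 1.88 TPM (limma, adjusted p = 1.19e-05) and CLDN1 2.64 ± 1.61 and 9.58 ± 0.794 TPM (limma, adjusted p = 7.3e-06). AKT1 was called higher by 0.36 log2 (limma, adjusted p = 0.00523), which median-of-ratios scaling turned to -0.02 (limma, adjusted p = 0.871).

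In all 7463 genes were called higher and 3067 lower by limma. Scaling by the median of ratios moved the median of all genes by 0.296 log2 and the split to 4750 higher and 5211 lower. Transcripts of the mitochondrial genome took 24.0, 23.1 and 14.5% of the TPM in the LoVo EV libraries and 8.67 ± 1.5% in LoVo-labelled LIN28B (SD, n = 3). Without LoVo EV replicates 1 and 2 together, an alternative added after seeing the data, 7306 genes were called.

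Groups of genes moved together under the LoVo label. All 13 mitochondrially encoded genes fell (13 adjusted over the list alone, camera adjusted p = 7.14e-07), and with them 21 of 34 interferon response genes, while 3 rose (22 and 3 adjusted over the list alone, camera adjusted p = 1.12e-07). The antiviral genes BST2 and MX1 fell by 4.44 and 2.90 log2. Genes of the MHC class I presentation list, which also held class II genes such as CD74, fell in 12 of 19 and rose in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 7.14e-07). With an estimated correlation the mitochondrial list had adjusted p = 0.467, and the interferon and MHC lists each had adjusted p = 0.142. All 34 mitosis genes rose, 28 of them under the scaling (34 adjusted over the list alone, camera adjusted p = 1.14e-08, and adjusted p = 0.357 with an estimated correlation). Cholesterol synthesis genes rose in 25 of 27 (25 adjusted over the list alone, camera adjusted p = 7.14e-07), ATF4 and amino acid response genes in 32 of 36 with 3 lower (32 and 4 adjusted over the list alone, camera adjusted p = 7.14e-07), and both had adjusted p = 0.467 with an estimated correlation. Hypoxia response genes rose in 21 of 23, the other 2, CA9 among them, fell (21 and 2 adjusted over the list alone, camera adjusted p = 5.52e-05), and glycolysis genes rose in 23 of 25 with 1 lower (23 and 1 adjusted over the list alone, camera adjusted p = 4.93e-05). These lists had adjusted p = 0.467 and adjusted p = 0.486 with an estimated correlation. Enterocyte markers rose in 14 of 15, for example the transcription factors HNF4A by 2.30 and KLF4 by 2.02 log2 (14 adjusted over the list alone, camera adjusted p = 9.23e-06, and adjusted p = 0.142 with an estimated correlation). Of the cytosolic ribosomal protein genes 7 rose and 35 of 77 fell (7 and 35 adjusted over the list alone), against 1 and 63 under the scaling (camera, adjusted p = 3.4e-06, and adjusted p = 0.467 with an estimated correlation). Of the PI3K/AKT/mTOR components 26 of 39 rose and 4 fell (27 and 4 adjusted over the list alone, camera adjusted p = 0.0316, and adjusted p = 0.527 with an estimated correlation), but 14 rose and 10 fell under the scaling (camera adjusted p = 0.133). Let-7 target mRNAs rose in 22 of 37 and fell in 6 (22 and 6 adjusted over the list alone), which camera did not call (adjusted p = 0.0878).

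Calls of LIN28B versus EV in the 2 lines were then set side by side, with no library shared. Of the genes higher in DLD-1 LIN28B, 167 of 225 were also higher under the LoVo label against 90.6 for independent lists (Fisher's exact test, p = 2.61e-25), and 100 of 244 were lower in both against 40.4 (Fisher's exact test, p = 6.74e-20). Opposed calls numbered 119. Of these, 99 were higher under the LoVo label and lower in DLD-1, against 98.2 for independent lists, and 20 were the reverse, against 37.2. Under median-of-ratios scaling the first kind numbered 127 against 98.1 (Fisher's exact test, p = 0.000532) and the second 34 against 73.1. Shared calls under that scaling were 162 higher against 66.6 and 183 lower against 108. The effects correlated at r = 0.0826 across genes, which are not independent replicates. Simulated unchanged groups gave 0.000264, which is near 0 by construction because no library is shared.

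Alpelisib versus untreated asked what PI3K inhibition changed in cells with LIN28B. DDIT4, an mTOR inhibitor induced by stress, fell from 1164 ± 180 to 96.2 ± 13.7 TPM in DLD-1 and from 3104 ± 197 to 441 ± 98.5 TPM in the LoVo-labelled libraries (SD, n = 3). HILPDA, a lipid droplet protein induced by hypoxia, fell from 174 ± 13.2 to 28.6 ± 4.91 TPM and from 607 ± 59.9 to 70.8 ± 8.58 TPM, and LGALS1, galectin 1, from 204 ± 13.4 to 41.1 ± 3.95 TPM and from 305 ± 15.9 to 61.0 ± 12 TPM. REG4, a secreted lectin of the gut, rose in DLD-1 from 3.14 ± 0.896 to 37.3 ± 2.53 TPM, and PSCA under the LoVo label from 6.66 ± 1.06 to 63.3 ± 14.4 TPM. IRS2, an adaptor of the insulin receptor, rose 1.78-fold and 1.76-fold, to 4.20 ± 0.551 and 5.46 ± 0.894 TPM. LIN28B itself fell, by 1.68 log2 in DLD-1 and by 2.15 in the LoVo-labelled libraries.

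In DLD-1, limma gave adjusted p = 3.06e-09 for DDIT4 (log2 -3.58), HILPDA (-2.58) and BHLHE40 (103 ± 2.6 to 15.2 ± 2.05 TPM), a circadian and hypoxia-responsive repressor, 2.56e-08 for LGALS1 (-2.28), 6.78e-09 for REG4 (3.23), 0.00401 for IRS2 (0.62) and 1.9e-06 for LIN28B. ANGPTL4, an inhibitor of lipoprotein lipase, fell by 2.46 log2 (limma, adjusted p = 2.5e-08), SLC7A11, the cystine transporter, by 2.38 (limma, adjusted p = 1.52e-07) and CHAC1 by 2.46 (limma, adjusted p = 8.24e-05). IL37, an interleukin, rose 6.16-fold (limma, adjusted p = 1e-07). PIK3R1, the regulatory PI3K subunit, fell by 0.99 log2 (20.2 ± 0.804 to 9.69 ± 1.2 TPM, limma, adjusted p = 0.000354) and PIK3CB, the beta catalytic subunit, from 20.5 ± 1.7 to 10.5 ± 0.616 TPM (limma, adjusted p = 0.000379). PIK3CA measured 11.7 ± 1.1 and 10.5 ± 1.2 TPM (limma, adjusted p = 0.496).

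In the LoVo-labelled libraries, limma gave adjusted p = 1.34e-08 for DDIT4 (log2 -2.83), 8.59e-11 for HILPDA (-3.08), 1.13e-08 for LGALS1 (-2.32), 3.48e-08 for PSCA (3.05), 0.00175 for IRS2 (0.66) and 6.6e-08 for LIN28B. SCD, the stearoyl-CoA desaturase, fell from 646 ± 39.2 to 85.2 ± 20.3 TPM and INSIG1, a regulator of sterol synthesis, from 328 ± 14.1 to 54.6 ± 13.5 TPM (limma, adjusted p = 7.91e-09 for both). ERRFI1, a feedback inhibitor of the EGF receptor, fell by 2.41 log2 (limma, adjusted p = 5.84e-08) and NR1D1, a circadian repressor, by 2.32 (limma, adjusted p = 8.59e-11). AVIL, an actin-binding protein, rose by 3.26 log2 (limma, adjusted p = 7.85e-09), SLC2A5, a fructose transporter, from 0.702 ± 0.534 to 9.68 ± 1.76 TPM (limma, adjusted p = 9.19e-07) and ERBB3, a receptor of neuregulins, by 0.52 log2 (limma, adjusted p = 0.000316). PIK3R1 measured 23.2 ± 1.88 and 12.2 ± 2.52 TPM (limma, adjusted p = 0.000393). PIK3CB fell by 0.62 log2 (limma, adjusted p = 0.00338), a call that the GC content and length correction ended (adjusted p = 0.0834).

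Genes of sugar and lipid metabolism fell with alpelisib in both lines. Glycolysis genes fell in 23 of 25 in each line (24 in DLD-1 and 23 in LoVo adjusted over the list alone, camera adjusted p = 1.45e-15 and 2.56e-12), among them ENO2, an enolase, by 1.22 log2 in DLD-1 and 1.32 under the LoVo label. Cholesterol synthesis genes fell in 23 of 27 in each (24 and 23 adjusted over the list alone, camera adjusted p = 1.03e-13 and 2.15e-12), with MSMO1, a sterol oxidase, at -1.54 and -1.64. Fatty acid synthesis genes fell in 11 and 13 of 20, and 0 rose (12 lower and 1 higher, and 13 lower, adjusted over the list alone, camera adjusted p = 0.000187 and 2.22e-07). With an estimated correlation the 3 lists had adjusted p = 0.317, 0.317 and 0.424 in DLD-1 and each had adjusted p = 0.321 under the LoVo label.

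Housekeeping genes, read as a control list, fell with alpelisib as well, by less: 11 of 24 in DLD-1 with 1 higher and 15 of 24 under the LoVo label (12 lower and 2 higher, and 15 lower, adjusted over the list alone), with medians of -0.28 and -0.41 log2 against -0.94 and -1.08 for glycolysis genes. Camera gave housekeeping genes adjusted p = 0.0293 and 0.000107, and adjusted p = 0.768 and 0.376 with an estimated correlation. Under the scaling their medians were -0.13 and -0.28 (camera adjusted p = 0.161 and 0.00104), and those of glycolysis genes -0.79 and -0.95. The mitochondrial share of the TPM was 10.6 ± 0.44% in DLD-1 LIN28B and 15.8, 14.8 and 10.6% in its alpelisib libraries.

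Stress and growth genes moved as well. Hypoxia response genes fell in 21 of 23 in each line and 1 rose (21 and 1 in each adjusted over the list alone, camera adjusted p = 1.69e-12 in DLD-1 and 1.72e-10 in LoVo). ATF4 and amino acid response genes fell in 32 and 30 of 36, and 1 rose in each (33 and 30 lower, 1 and 2 higher, adjusted over the list alone, camera adjusted p = 4.31e-18 and 3.19e-10), with PSAT1, an enzyme of serine synthesis, at -1.72 and -1.63. Mitosis genes fell in 30 and 34 of 34 (31 and 34 adjusted over the list alone, camera adjusted p = 8.27e-15 and 2.79e-19), CDC20, an activator of the anaphase-promoting complex, by 0.86 and 1.13. With an estimated correlation these 3 lists each had adjusted p = 0.287 in DLD-1 and adjusted p = 0.321 in LoVo. Unfolded protein response genes fell in 17 and 19 of 21 (18 and 20 adjusted over the list alone, camera adjusted p = 8.12e-07 and 5.4e-09, and adjusted p = 0.424 and 0.321 with an estimated correlation).

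Cytosolic ribosomal protein genes rose, 50 of 77 in DLD-1 and 59 of 77 in the LoVo-labelled libraries with 0 lower (56 and 62 adjusted over the list alone), with medians of 0.34 and 0.40 log2. RPL13 rose by 0.56 and 0.66. Under the scaling 69 and 71 rose. Camera gave adjusted p = 4.24e-26 and 2.02e-22, and adjusted p = 0.287 and 0.321 with an estimated correlation. Their share of the TPM went from 18.5 ± 0.55 to 23.2 ± 0.9% in DLD-1 and from 18.6 ± 0.2 to 24.5 ± 0.44% under the LoVo label (SD, n = 3). PI3K/AKT/mTOR components fell in 13 and 17 of 39 while 0 and 2 rose (14 and 18 lower, 0 and 2 higher, adjusted over the list alone, camera adjusted p = 0.0293 and 0.0069, and adjusted p = 0.768 and 0.488 with an estimated correlation). In DLD-1 that camera call ended under the scaling (adjusted p = 0.0915). Let-7 target mRNAs were not called by camera in either line (adjusted p = 0.297 in DLD-1 and 0.605 under the LoVo label), with 3 higher and 15 lower and with 9 higher and 14 lower of 37 (3 and 15, and 9 and 15, adjusted over the list alone).

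**Figure D5:**
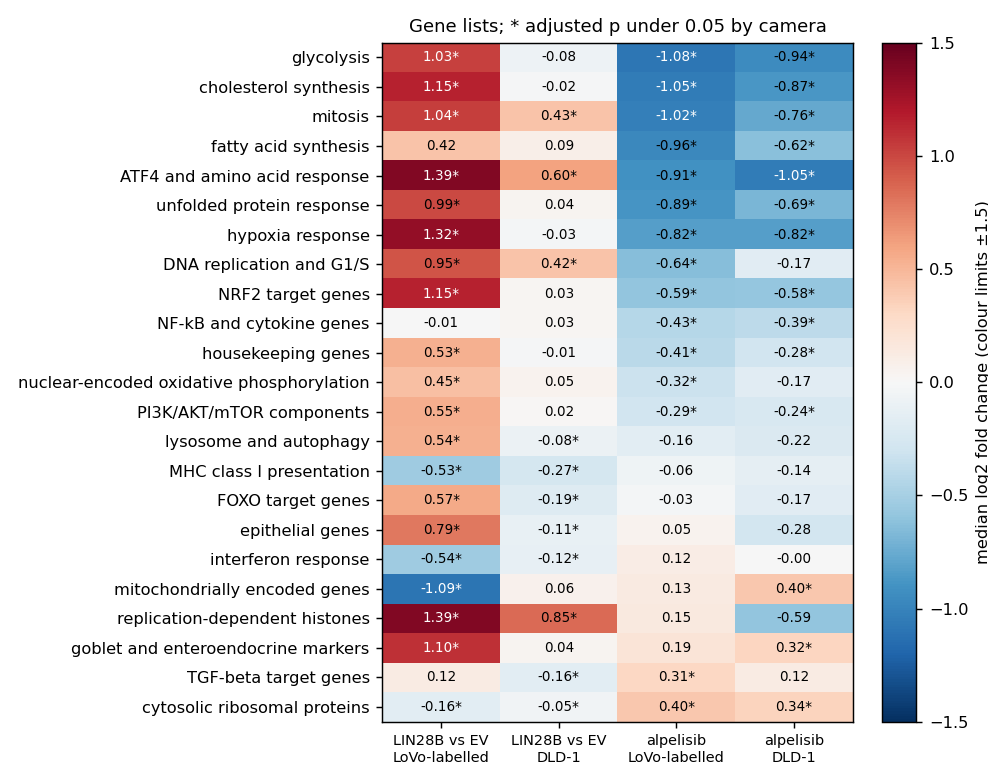
Median log2 fold change of 23 gene lists (lines) in LIN28B versus EV and alpelisib versus untreated in each line (columns), with colours limited at ±1.5; a star marks a camera adjusted p under 0.05 at the preset correlation. Ribosomal protein genes had medians of 0.34 and 0.40 with alpelisib and glycolysis genes -0.94 and -1.08, in DLD-1 and under the LoVo label.

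In all, limma called 1677 genes higher and 4067 lower with alpelisib in DLD-1, and 2807 higher and 4557 lower in the LoVo-labelled libraries. Scaling moved the median of all genes by -0.109 log2 in DLD-1 and by -0.0966 under the LoVo label, and gave 2686 higher and 2819 lower and 3699 higher and 3639 lower. Both labels called 1232 genes higher and 3088 lower, against 254 and 1000 for independent lists, and 18 in opposite directions. This overlap may not be one between separate lines. The effects correlated at r = 0.704 across genes, which are not independent replicates. Simulated unchanged groups gave 0.000933, which is near 0 by construction because these comparisons share no library.

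Opposition of the LIN28B and alpelisib effects was examined as a question of the design. No EV cells received alpelisib, so whether cells without LIN28B overexpression would change alike cannot be told. LIN28B itself fell with alpelisib, from 462 to 143 TPM in DLD-1 and from 687 to 154 TPM under the LoVo label. Opposition through PI3K inhibition and opposition through less LIN28B mRNA can therefore not be told apart here. Of the genes higher in DLD-1 LIN28B, 161 of 225 fell with alpelisib in the LoVo-labelled libraries, which share no library with them, against 55.3 for independent lists (Fisher's exact test, p = 3.26e-50). Of those lower, 133 of 244 rose, against 36.9 (Fisher's exact test, p = 9.91e-47). Genes called the same way numbered 13 and 29, against 34.1 and 60. PSCA and ASNS were among the opposed: PSCA fell with LIN28B in DLD-1 and rose with alpelisib under the LoVo label, and ASNS rose with LIN28B in DLD-1 and fell with alpelisib under the LoVo label.

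Within DLD-1, where both comparisons use the LIN28B libraries, 123 of 225 and 107 of 244 were opposed, against 49.4 and 22.1 for independent lists. The correlation across genes was -0.303, against -0.503 in simulated unchanged groups, and the covariance was -0.0477 against a simulated -0.0322, a difference of -0.0156. Under the LoVo label 3634 and 987 genes were opposed, against 1830 and 464 for independent lists, with r = -0.419 against a simulated -0.506 and a covariance of -0.222 against -0.0327, a difference of -0.189. Splitting the 3 shared libraries would leave 1 in a part, so part of the excess over independent lists may come from the shared libraries.

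LIN28B with alpelisib versus EV in DLD-1 joined the effects of LIN28B and of the drug. Without EV cells given alpelisib, this comparison cannot tell them apart. LIN28B was still 81.3-fold higher than in EV and HMGA2 1.98-fold higher, at 36.4 ± 1.91 against 18.4 ± 0.977 TPM (SD, n = 3; limma, adjusted p = 7.8e-13 and 2.46e-05). IGF2BP2 measured 60.0 ± 2.03 and 60.9 ± 1.95 TPM (limma, adjusted p = 0.857). PIK3CB and PIK3R1 were lower by 1.02 and 0.95 log2 (limma, adjusted p = 0.000152 and 0.000458) and the receptor NOTCH3 by 0.91 (limma, adjusted p = 0.00182). Ribosomal protein genes were higher in 45 of 77 (48 adjusted over the list alone), and glycolysis genes lower in 24 of 25 (24 adjusted over the list alone), cholesterol synthesis genes in 23 of 27 (24) and hypoxia response genes in 21 of 23 with 1 higher (21 and 1). Camera gave these 4 lists adjusted p = 3.66e-19, 9.24e-18, 1.55e-14 and 1.37e-13, and each had adjusted p = 0.405 with an estimated correlation. DNA replication and G1/S genes were higher in 13 of 42 and lower in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 4.22e-05, and adjusted p = 0.553 with an estimated correlation). In all 1800 genes were higher and 3740 lower by limma, and 2657 and 3006 under the scaling.

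Under the LoVo label, LIN28B with alpelisib was set against LoVo EV, with the same limit. LIN28B was 37.1-fold higher, ERBB3 measured 85.8 ± 5.91 against 43.4 ± 0.618 TPM and HMGA2 31.7 ± 3.25 against 65.0 ± 9.04 TPM (SD, n = 3; limma, adjusted p = 3.98e-13, 2.1e-07 and 1.54e-06). CLDN1 was higher by 1.59 log2 (limma, adjusted p = 1.31e-05). Enterocyte markers were higher in 14 of 15 (14 adjusted over the list alone) and interferon response genes lower in 21 of 34 with 2 higher (22 and 2 adjusted over the list alone). Camera gave adjusted p = 1.85e-07 and 4.14e-09, and both had adjusted p = 0.0871 with an estimated correlation. Ribosomal protein genes were higher in 45 of 77 (48 adjusted over the list alone, camera adjusted p = 0.000844, and adjusted p = 0.844 with an estimated correlation), but in 15, with 7 lower, under the scaling (camera adjusted p = 0.702), which moved the median of all genes by 0.2 log2. In all 5962 genes were higher and 2719 lower by limma, and 4089 and 4387 under the scaling. Without LoVo EV replicates 1 and 2 together 6273 were called, as an alternative added after seeing the data.

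Differences of effects between lines were tested directly. For LIN28B versus EV, limma called 7923 genes, 2296 with a higher and 5627 with a lower effect in DLD-1 than under the LoVo label, or 3822 and 3544 under the scaling, which moved the median by -0.274 log2. HMGA2 had the higher effect in DLD-1, by 2.18 log2 (limma, adjusted p = 3.12e-08). CLDN1 had the lower effect, at -1.48 (limma, adjusted p = 0.000922). The difference of LIN28B itself was not called (0.35, limma, adjusted p = 0.201), although without DLD-1 EV replicate 1 it was (adjusted p = 0.00391).

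For alpelisib, limma called 157 genes, 39 with a higher and 118 with a lower effect in DLD-1, or 105 and 169 under the scaling. In simulated data this test recovered 10.4% of 1.5-fold, 43.3% of 2-fold and 77.3% of 4-fold differences. REG4 rose more in DLD-1 than under the LoVo label, by 1.96 log2 (limma, adjusted p = 0.00103), and SLC26A2, a sulfate transporter, had the lower effect in DLD-1, at -1.96 (limma, adjusted p = 9.17e-05): it went from 9.92 ± 0.553 to 36.8 ± 4.17 TPM under the LoVo label and from 4.06 ± 0.249 to 3.48 ± 0.0429 TPM in DLD-1 (SD, n = 3). LIF, a cytokine of the interleukin 6 family, had a difference of 1.21 (limma, adjusted p = 0.0047). DNA replication and G1/S genes had a median difference of 0.53 log2 (1 of 42 called, 17 adjusted over the list alone, camera adjusted p = 1.13e-16, and adjusted p = 0.455 with an estimated correlation): they fell in 35 of 42 under the LoVo label (camera adjusted p = 6.54e-09, and adjusted p = 0.35 with an estimated correlation) and in 7 of 42, with 1 higher, in DLD-1 (camera adjusted p = 0.482). PCNA, the sliding clamp of DNA polymerase, was the 1 gene called (difference 0.72, limma, adjusted p = 0.0119), chosen after its values were seen. The count of 157 was 95 without LoVo LIN28B replicate 1, 101 without LoVo LIN28B alpelisib replicate 2, 91 without DLD-1 LIN28B replicate 1, and 82 and 104 without DLD-1 LIN28B alpelisib replicates 1 and 2.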

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

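The tests chosen after the results were seen were both tests on genome bins, the scaling tests of the ribosomal protein genes and of LIN28B, and all counts of other splits of the samples. The alternatives without LoVo EV replicates 1 and 2, without mitochondrially encoded genes and with the GC content and length correction were added after seeing the data, and the list of TOP mRNAs was drawn up then too.

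The libraries labelled LoVo LIN28B lay closer to DLD-1 than to LoVo EV, and the mitochondrial share, GC content and length are argued against as the whole cause of this: without mitochondrial genes 10256 genes were called, 9099 of them among the 10530, and after the GC content and length correction 9495, with 7940 of the 10530 among them. Different cell lines behind the LoVo EV and LoVo LIN28B labels are a candidate explanation, since the difference followed regions of the genome: its SD over bins was 1.8 times the mean with genes shuffled between bins (0 of 1000 shuffles as large), beside 1.81 for DLD-1 EV against LoVo EV. The profiles of these 2 differences correlated at r = 0.832 over 131 bins, which are not independent replicates, and at 0.755 with separate LoVo EV libraries on each side, but both are differences from LoVo EV and so share its profile. For LIN28B as the whole cause this ratio could not decide, because changes within a label also followed regions to a degree. It was 1.39 times the highest of their ratios, 1.29 for alpelisib in DLD-1. The SD over bins was 0.0611 between LoVo-labelled LIN28B and DLD-1 EV (0.0555 to 0.0771 over pairs of single libraries). Between DLD-1 EV and LoVo EV it was 0.148 (0.133 to 0.185), and between DLD-1 LIN28B and EV 0.0332. LIN28B would thus have had to remove much of the regional difference in LoVo while changing regions little in DLD-1. These values argue against LIN28B as the whole cause. Which of the LoVo-labelled sets may be out of place stays open, as does a difference between clones of a line, which was not tested.

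Ribosomal protein mRNAs rose with alpelisib under both line labels, which may not stand for separate lines. A bias of GC content and length as the whole cause is argued against by a median that stayed at 0.346 log2 or more after that correction, and the scaling to total TPM by a median of 0.497 or more under median-of-ratios scaling. Both lines also raised the other mRNAs known to start with a 5 prime terminal oligopyrimidine (TOP) motif, a class whose translation depends on mTOR: 13 of 27 rose and 1 fell under the LoVo label and 10 rose and 1 fell in DLD-1, with medians of 0.22 and 0.19 log2 above 99.99% and 99.39% of 10000 random lists matched on expression. As a hypothesis, a response of TOP mRNAs as a class may underlie the pattern. RNA stability and translation were not measured.

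LIN28B mRNA fell with alpelisib under both line labels, with the same limit. Scaling is argued against as the whole cause, since the smaller fall stayed at -1.52 log2 under median-of-ratios scaling, and so is a general fall of mRNAs at that level, since at most 1.46% of genes between 200 and 1000 TPM (7 of 480, and 5 of 462 in DLD-1, or 1.08%) fell as much. A response of the promoter that drives the introduced LIN28B, or of LIN28B mRNA stability, stays open and was not tested, because the construct was not given in the sources used here.

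Regrouping the samples gave these values. In each comparison of 3 libraries against 3, the real grouping was 1 of 10, too few for a share under 0.05: LIN28B versus EV called 10530 genes in LoVo against 2 in the highest other split and 469 in DLD-1 against 1, alpelisib called 7364 under the LoVo label against 1 and 5744 in DLD-1 against 0, and LIN28B with alpelisib versus EV called 8681 under the LoVo label against 1492 and 5540 in DLD-1 against 1. Each other split mixed both real groups on both sides. A difference between those groups, whatever its cause, then widens the spread and lowers the calls, so the gap in counts is no evidence on cause. For the differences between lines, 100 of 200 possible splits were drawn, and 5 gave as many genes as the 7923 for LIN28B (highest other 8685) and 8 as many as the 157 for alpelisib (highest other 9186), the real one included. All of these kept the real groups of at least 1 line, and a split that keeps only 1 line's groups can leave that line's effect in the difference. These counts therefore cannot decide on chance, which was not excluded. Of 80 splits that kept neither line's groups, the highest gave 1 and 2 genes.

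Genes whose LIN28B effect differed between the lines, with the log2 effect in DLD-1 minus that under the LoVo label, numbered 7923 by limma. TFF3 (-5.46), NDUFA4L2 (-5.22), FAM3D (-5.08), KIT (-5.02) and SLC39A2 (-5.01) had the lower effect in DLD-1. CD74 (6.41), SUGCT (6.06), GTSF1 (5.85) and AKAP12 (5.37) had the higher effect in DLD-1, as did TNFRSF6B (6.29), which was listed at 0 in each library outside LoVo EV, where it had 77.6 ± 8.57 TPM (SD, n = 3). TFF3 and KIT measured 63.0 and 41.2 TPM in LoVo-labelled LIN28B, near DLD-1 EV (65.7 and 40.1 TPM) and far from LoVo EV (0.702 and 0.540 TPM). LoVo EV was also the group apart for CD74, SUGCT, GTSF1 and AKAP12. For NDUFA4L2, FAM3D and SLC39A2, LoVo-labelled LIN28B lay apart instead (85.7, 16.8 and 41.7 TPM, against 3.68, 2.83 and 0.0738 TPM in DLD-1 EV). These differences therefore need not be responses to LIN28B that are particular to a line. Among the genes named in each comparison, HMGA2 differed by 2.18, PIK3CA by -1.10, PIK3R1 by -1.12, CLDN1 by -1.48 and ERBB3 by -0.89. PIK3CB differed by -0.76 (limma, adjusted p = 0.00813), a call that ended under median-of-ratios scaling (adjusted p = 0.0808), quantile normalization (0.0661), the GC content and length correction (0.297) and without LoVo EV replicates 1 and 2 together (0.065).

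Genes whose alpelisib effect differed between the lines, in the same direction of subtraction, numbered 157 by limma. SLC26A2 differed by -1.96, DIO3 by -1.95, REG4 by 1.96 and LIF by 1.21. CALML5 differed by -2.30, which a pseudocount of 0.1 ended (limma, adjusted p = 0.16), and PLA2G12A, a phospholipase gene, by 1.17. KALRN differed by -1.85 (limma, adjusted p = 0.0247) and lost the call without LoVo LIN28B replicate 3 (0.0627), LoVo LIN28B alpelisib replicate 1 (0.0574), DLD-1 LIN28B replicates 1, 2 and 3 (0.05, 0.0561 and 0.0704) or DLD-1 LIN28B alpelisib replicates 1 and 2 (0.0715 and 0.0528). RAMP1 differed by 1.73 (limma, adjusted p = 0.026) and lost it without LoVo LIN28B replicates 2 and 3 (0.054 and 0.0636), LoVo LIN28B alpelisib replicate 3 (0.0509), DLD-1 LIN28B replicates 1 and 3 (0.0571 and 0.0736) or DLD-1 LIN28B alpelisib replicates 1, 2 and 3 (0.0532, 0.0686 and 0.0556). PRADX differed by 1.15 (limma, adjusted p = 0.0229) and lost it without LoVo LIN28B replicates 1 and 2 (0.0662 and 0.0638), LoVo LIN28B alpelisib replicates 1 and 2 (0.0536 and 0.0515), DLD-1 LIN28B replicates 1 and 3 (0.0544 and 0.0663) or DLD-1 LIN28B alpelisib replicates 1 and 3 (0.0698 and 0.0508).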

How the results depend on the processing

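All alternatives were planned except those without LoVo EV replicates 1 and 2 together, without mitochondrially encoded genes and with the GC content and length correction, which were chosen after seeing the data. The 469 genes called for LIN28B versus EV in DLD-1 became 290 with no filter, 756 with the GC content and length correction, 1003 with array quality weights and 183 in a fit of only the groups compared, and 185 to 229 with 1 library left out. The 157 genes of the alpelisib difference became 274 under median-of-ratios scaling, 292 under quantile normalization, 338 with the GC content and length correction and 402 with array quality weights, and 82 to 155 with 1 library left out. Leaving out 1 library gave 9477 to 10738 genes for LIN28B versus EV and 5835 to 6884 for alpelisib under the LoVo label, 4013 to 5238 for alpelisib in DLD-1, 7638 to 9024 (LoVo) and 3872 to 5094 (DLD-1) for LIN28B with alpelisib versus EV, and 7065 to 8709 for the LIN28B difference. Without LoVo EV replicates 1 and 2 together, where the lone sample is assumed to vary like the other groups, LIN28B versus EV under the LoVo label called 7306 genes and its difference 5458. Without mitochondrially encoded genes the 2 LIN28B versus EV comparisons called 10256 and 587 genes and alpelisib 7492 and 5776, in LoVo and DLD-1. Camera called 24, 14, 15 and 15 lists for LIN28B in LoVo and DLD-1 and alpelisib in LoVo and DLD-1, and 0 in each with an estimated correlation. With a fold minimum of 1.5, which takes fewer genes by construction, the 267 LIN28B calls shared by the lines became 122, the 4320 alpelisib calls 2164, the 4621 and 230 opposed calls in LoVo and DLD-1 2518 and 86, and the 294 opposed calls of DLD-1 LIN28B and LoVo alpelisib 114. The cause of the other changes was not tested.

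Same-numbered libraries were not paired by their values: over 18 pairs, r of deviations from the group means ranged from -0.3 to 0.12, 1 pair exceeded 0.1, and 4 libraries matched best with their own number. The replicate block moved the 469 genes to 170, the 157 to 41, the 267 shared calls to 91, the 230 opposed calls to 87 and the 294 to 103, and changed no other count by over 1.5 times. PLA2G12A lost its call under it (adjusted p = 0.0843).

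Of 8117 values of named genes under other settings, 7694 kept direction and side of the threshold, 230 lost the call, 183 gained one and 10 changed sign. With 1 library left out, 4724 of 5070 kept both, 319 lost the call, 27 gained one and 0 changed sign. In LIN28B versus EV in LoVo, AKT1 turned to -0.018 under median-of-ratios scaling and -0.037 under quantile normalization, and AKT2 to -0.28 and -0.31. CLDN3 turned to -0.014 with alpelisib in LoVo under the GC content and length correction, and MT-CO1 to 0.000 with alpelisib in DLD-1 under quantile normalization. IGF2BP2 turned to -0.039 (scaling) and -0.029 (GC content and length) in LIN28B with alpelisib versus EV in LoVo, and in the LIN28B difference IGF2BP2 turned to 0.29 and AKT2 to 0.37 under quantile normalization. The cause was not tested. Depth is unknown, and low genes are limited by the pseudocount.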

Other observations

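The comparisons and lists of this part were fixed in advance, and the lists and genes given here were picked after their values were seen. LGR5, a receptor of intestinal stem cells, rose with alpelisib by 1.28 log2 under the LoVo label and 1.36 in DLD-1 (limma, adjusted p = 4.54e-07 and 6.82e-07). Intestinal stem cell markers as a list were not called by camera (adjusted p = 0.0783 and 0.12), with 6 higher and 2 lower of 14 under the LoVo label (6 and 4 adjusted over the list alone) and 3 higher and 3 lower in DLD-1 (3 and 3). CD24, a surface glycoprotein, rose by 1.64 and 0.37.

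Genes of the ERK pathway output went both ways with alpelisib. SPRY4, a feedback inhibitor of receptor kinases, rose by 1.94 log2 under the LoVo label and 1.18 in DLD-1, while DUSP5, a phosphatase of ERK, fell by 1.25 and 1.34 and PHLDA1 by 1.19 and 0.97. The list held 4 higher and 13 lower of 22 under the LoVo label (5 and 13 adjusted over the list alone) and 3 higher and 14 lower in DLD-1 (4 and 15), and camera did not call it (adjusted p = 0.103 and 0.12). The p53 target genes were not called by camera either (adjusted p = 0.167 and 0.154), with 2 higher and 9 lower of 27 under the LoVo label and 1 higher and 9 lower in DLD-1 (the same numbers adjusted over the list alone). CDKN1A, a cell cycle inhibitor, fell by 1.28 and 2.28, and TP53I3, an oxidoreductase, was among the few that rose, by 1.22 and 0.97.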
